A study of Homo sapiens with 12 samples.

How the data were processed

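RNA was measured in 12 libraries of electroporated human primary activated pan T cells, 3 for each of the 4 groups mock, GFP_mRNA, cssDNA and dsDNA. Per the labels' protocols, poly(A) RNA was selected and sequenced as paired ends on an Illumina instrument. The deposited table holds raw read counts per gene, as the authors made them, without normalization; the values are whole numbers whose sums differ between libraries. Per the submitters' processing notes the genome build was GRCh38, while the aligner, the counting program and the strand setting are not given in the sources used here. Each column was assigned to its sample by the group and number in its name, and all 12 columns were used. The delivered mRNA and the DNA templates themselves were not analysed here.

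The table lists 58735 genes, of which 58207 identifiers were found in the reference annotation. A group of 520 sex-linked genes was left out of every test. Totals were 14284832 to 23858015 counts per library, at which 3 counts, the 95% upper limit that a count of 0 allows, correspond to 0.126 to 0.210 CPM, the count scaled to library size. Genes were kept by edgeR's filterByExpr, which left 15818, and scaled by TMM. Differences were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test in 1 fit of all 12 libraries with a coefficient per group, 8 residual degrees of freedom and 13.8 prior degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05, with no fold minimum. The biological coefficient of variation over all groups was 20.8%. The log2 fold changes are those of edgeR's fit at its default prior count, and CPM values are given as mean ± SD of 3 libraries. The standard error (SE) of the fold changes was computed from the residual SD of log2 CPM, with a prior count of 2, over the 12 libraries. For genes with few counts the fold change and its SE are therefore on unlike scales. No pair of libraries within a group had counts as alike as a repeat of 1 library would have, with a chi-square per degree of freedom of 7.10 to 28.6. Correlations of log2 CPM within groups were 0.975 to 0.979 in mock, 0.965 to 0.976 in GFP_mRNA, 0.953 to 0.961 in cssDNA and 0.946 to 0.956 in dsDNA.

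The 6 comparisons, the 30 gene lists with 742 symbols, the tests and the first set of alternatives below were chosen before the data were examined. The lists cover interferon genes and interferon-stimulated genes, DNA and RNA sensing, NF-kB targets, chemokines, cytokines, p53 targets, apoptosis, DNA repair, T cell activation, checkpoint receptors, cytotoxic effectors, naive and memory, CD4 and CD8 T cell identity, cell cycle, stress responses, antigen presentation, metabolism, mitochondrial, ribosomal and histone genes, and markers of other blood cells. Of the listed genes, 721 were in the table, and the 28 lists with at least 5 tested members were tested with camera of limma 3.58.1 with a preset correlation of 0.01, and again with a correlation estimated per list; members called were also counted with p-values adjusted over the list alone. Genes were named by a rule: per comparison the 10 largest increases and the 10 largest decreases among called protein-coding genes with a mean of at least 1 CPM and no overlap between the groups' libraries, per comparison and list up to 4 members with the smallest adjusted p, and a fixed set (IFNB1, IFNG, ISG15, IFIT1, MX1, OAS1, CXCL10, CGAS, STING1, IFIH1, CDKN1A, CD69, CD4, CD8A, GZMB, ATF3, MKI67). The text names part of these, and no immunoglobulin or T cell receptor segment. Some single-gene results are not reported here.

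The alternatives of that set were RLE size factors, DESeq2 1.42.0, limma-voom, no expression filter beyond 1 count in any library, a filter of 5 CPM in 3 libraries, a fold of at least 2, a fit of only the groups compared, a block on the replicate number, each library left out in turn, and for lists the estimated correlation. Added after the data were seen were limma-voom with library quality weights, the mitochondrial share as a covariate, a correction of log2 CPM for GC content and transcript length with limma-trend, and limma-voom for the overlap. The overlap of 2 comparisons with the same mock libraries was set against 40 simulations in which neither group differs from mock. The test was tried on simulated data with known changes and 1 spread for all groups. At this depth and n it recovered 28.4% to 49.3% of genes changed 1.5-fold, 53.0% to 70.1% of those changed 2-fold and 63.6% to 78.8% of those changed 4-fold. Of its calls, which include p53 targets raised 1.3-fold, 3.08% to 8.66% were false. The real groups differed in spread, with a biological coefficient of variation of 14.3% in mock and 29.3% in dsDNA, so these rates may not hold for the real comparisons. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.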

Results

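RNA sequencing of poly(A) RNA measured gene expression in activated human primary pan T cells, a culture of CD4 and CD8 T cells together. The cells had been electroporated, a procedure in which an electric pulse opens the cell membrane to nucleic acids. In the mock group they received buffer only, which controls for the effect of electroporation itself. The other groups received mRNA coding for green fluorescent protein (GFP_mRNA), circular single-stranded DNA (cssDNA) or double-stranded DNA (dsDNA), both of the DNA forms being donor templates of the kind used in genome editing. Each of the 4 groups had 3 libraries, and counts were given for 58735 genes. The total count per library was 18682090 to 22630857 in mock, 18210547 to 23858015 in GFP_mRNA, 16762004 to 18135531 in cssDNA and 14284832 to 19588058 in dsDNA. Of these genes, 15818 had enough counts to be tested.

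The libraries of a group resembled each other less in the DNA groups than in mock. The biological coefficient of variation was 14.3% in mock, 18.2% in GFP_mRNA, 22.9% in cssDNA and 29.3% in dsDNA. The share of counts from mitochondrial genes, which is read as a sign of RNA and cell quality, was 2.55% ± 1.56 (SD, n = 3) in mock, 3.40% ± 0.775 in GFP_mRNA, 4.30% ± 0.247 in cssDNA and 2.71% ± 0.178 in dsDNA. In this share mock 3 stood apart from its group with 4.35%, against 1.79% in mock 1 and 1.52% in mock 2. Over all tested genes other libraries stood apart. On the 1st principal component dsDNA 3 lay at 92.6, against at most 23.7 in dsDNA 1 and dsDNA 2. Its correlation across genes was 0.955 with mock 1 and 0.956 with mock 2, above the 0.948 with dsDNA 1 and 0.946 with dsDNA 2. This did not set dsDNA 3 apart, since every other DNA library also correlated better with mock 2 than with its own group. For dsDNA 1 the values were 0.962 with mock 2 and 0.956 with dsDNA 2, and for cssDNA 2 they were 0.967 with mock 2 and 0.961 with cssDNA 3. On the 3rd component cssDNA 1 lay at −70.1, against −7.55 in cssDNA 2 and −3.91 in cssDNA 3. The number of genes with at least 1 count was 20075 to 20477 in mock, 18141 to 20929 in GFP_mRNA, 17730 to 18800 in cssDNA and 16454 to 18088 in dsDNA. With every library thinned to the smallest total, it was 19646 to 20033 in mock and 17892 to 20515 in GFP_mRNA. In cssDNA it was then 17649 to 18699, and in dsDNA 16376 to 18088. Depth alone therefore does not account for the lower numbers in the DNA groups than in mock, and their cause was not tested. Because no separate donors or cultures are named for the libraries, p-values measure only the spread between these libraries.

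The first comparison asked what GFP mRNA added to electroporation alone. The interferon-stimulated genes, which cells switch on in answer to foreign nucleic acids, were at the level of mock: MX1 was at 41.3 ± 2.71 CPM (counts scaled to library size; SD, n = 3) in GFP_mRNA and 44.3 ± 3.50 in mock, and ISG15 had a log2 fold change of 0.19 ± 0.13 (SE). None of the 47 tested interferon-stimulated genes passed the test, nor did any of the 33 p53 targets, 40 cell cycle genes or 17 genes of RNA sensing. CD8A (log2 fold change 0.07 ± 0.06, SE), CD4 (−0.07 ± 0.09), IFIH1 (−0.04 ± 0.16), CXCL10 (−0.05 ± 0.54), ATF3 (0.00 ± 0.15) and CDKN1A (0.18 ± 0.12) did not pass it either. The number of genes called was 1 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). At an unadjusted p under 0.05 there were 425 genes, DESeq2 called 2 and limma-voom 1. The count rose to 2 without mock 1 and to 18 without mock 3.

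Among the lists fixed beforehand, the cytosolic ribosomal proteins (median log2 fold change 0.14), the mitochondrial mRNAs (0.47), the chemokines (0.43), the T cell activation genes (0.10) and the CD8 T cell identity genes (0.10) stood above the other genes in limma's camera test with a preset correlation, with 0 members called over all genes. Adjusted over the list alone, 2 ribosomal protein genes passed and 0 genes of the other 4 lists. With an estimated correlation none of these 5 lists passed: adjusted p = 0.357 for the ribosomal proteins, the mitochondrial mRNAs and T cell activation, 0.351 for the chemokines and 0.308 for CD8 identity. Without mock 1 the number of lists was 2, and without GFP_mRNA 1 it was 3. All 13 mitochondrial mRNAs were called higher without mock 3, and 0 without any other 1 of the 6 libraries. The lists that stood higher here include the mitochondrial mRNAs, in which mock 3 stands apart from mock 1 and mock 2.

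The comparison of cssDNA with mock asked what the single-stranded circle added to electroporation. Genes activated by p53, the transcription factor that answers DNA damage and other stress, rose: BBC3, which codes for the pro-apoptotic protein PUMA (ENSG00000105327, GRCh38 chromosome 19, 47220822 to 47232766), went from 32.0 ± 2.33 CPM (SD, n = 3) in mock to 76.4 ± 6.21 in cssDNA, a log2 fold change of 1.26 ± 0.10 (SE). ZMAT3, an RNA-binding target of p53, rose by 0.75 ± 0.11, GADD45A, a growth arrest and DNA damage gene, by 0.96 ± 0.14, and TRIM22, which both p53 and interferon induce, by 0.63 ± 0.03. Of the 33 tested p53 targets 21 rose and 0 fell, with a median log2 fold change of 0.50, and 28 passed adjusted over the list alone. CDKN1A, the p53 target that halts the cell cycle, had a log2 fold change of 0.35 ± 0.12 and did not pass (adjusted p = 0.0502, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), though it was called with DESeq2, limma-voom or RLE size factors. Adjusted p for the same test was 2.09e-06 for BBC3, 0.000284 for ZMAT3, 0.000394 for GADD45A and 5.54e-06 for TRIM22. The list passed camera with a preset correlation (adjusted p = 4.38e-26) and with an estimated one (4.36e-05). The mitochondrial share moved with this group; with it as a covariate, added after the data were seen, the p53 median was 0.50 and 10 members were called.

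Cell cycle genes fell in cssDNA. MCM6, a subunit of the replicative helicase, went from 310 ± 13.7 to 217 ± 2.81 CPM (SD, n = 3; log2 fold change −0.52 ± 0.06, SE), and 22 of 40 list members fell and 0 rose, with a median of −0.34. A total of 34 fell adjusted over the list alone. DNA repair genes fell in 7 of 33 cases, 13 adjusted over the list alone, with a median of −0.17. MSH6, a mismatch repair gene (−0.44 ± 0.08), was among them. Genes of cholesterol and fatty acid synthesis fell in 6 of 27 cases, 10 adjusted over the list alone: FADS2, a fatty acid desaturase, changed by −0.43 ± 0.05 and FADS1 by −0.36 ± 0.05. MKI67, a marker of proliferating cells, had a log2 fold change of −0.23 ± 0.08 and did not pass (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0905). All 3 lists held in camera with an estimated correlation, with adjusted p = 0.000781 for the cell cycle, 0.0127 for DNA repair and 0.0141 for cholesterol synthesis. The cell cycle count was 14 without mock 2, and the DNA repair count was 4 without mock 1, mock 2 or cssDNA 1. With the mitochondrial share as a covariate 4 cell cycle genes were called, the median being −0.31, and the call for MSH6 was lost.

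Genes that mark CD8 T cells and cytotoxic function fell in cssDNA. CD8A, the alpha chain of the CD8 coreceptor (ENSG00000153563, GRCh38 chromosome 2, 86784610 to 86808396), went from 956 ± 37.8 to 687 ± 38.3 CPM (SD, n = 3; log2 fold change −0.48 ± 0.06, SE). PRF1, which codes for the pore-forming protein perforin, changed by −0.51 ± 0.05, NKG7, a protein of cytotoxic granules, by −0.43 ± 0.04, CTSW, a protease of cytotoxic cells, by −0.48 ± 0.06, and ZNF683, a transcription factor of resident and effector T cells, by −0.90 ± 0.15. Of 11 CD8 identity genes 3 fell and 0 rose, also adjusted over the list alone (median −0.38). Of 20 cytotoxic effectors 6 fell and 1 rose (8 and 1 adjusted over the list alone; median −0.40), the riser being FGFBP2 at 0.88 ± 0.11. CD4 had a log2 fold change of 0.24 ± 0.09 and GZMB, coding for granzyme B, of −0.27 ± 0.13, and neither passed (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.147 and 0.144). Of 11 CD4 identity genes 1 rose, a count that was 0 with any 1 of the 6 libraries left out. Both falling lists held in camera with an estimated correlation, with adjusted p = 0.0127 for CD8 identity and 0.0162 for the cytotoxic effectors. The lists share EOMES, GZMH, GZMK, KLRK1 and NKG7, so they are not independent here or in the other comparisons. NKG7 is counted as falling in both. Of 13 tested markers of natural killer cells, NCR3 was the 1 called, with −0.53 ± 0.05.

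Among the genes that rose in cssDNA were those of the transcription factor AP-1 and some of the stress response. FOS went from 18.9 ± 5.76 to 62.4 ± 16.5 CPM (SD, n = 3; log2 fold change 1.72 ± 0.31, SE), and FOSB (1.46 ± 0.22) and JUN (1.35 ± 0.19), which with it form the transcription factor AP-1, rose too. PPP1R15A (0.87 ± 0.10) and ATF3 (0.95 ± 0.15), both of the integrated stress response, rose, as did TNFSF4, the ligand of the costimulatory receptor OX40 (1.43 ± 0.14), BMF, a pro-apoptotic protein of the BCL2 family (1.20 ± 0.20), and CCR7 (0.53 ± 0.06) and TCF7 (0.52 ± 0.07), which mark naive and memory T cells. Of 32 activation genes 10 rose and 4 fell, among them TFRC, the transferrin receptor (−0.44 ± 0.06); of 26 genes of the integrated stress response 4 rose, of 18 naive and memory genes 6, and of 28 NF-kB targets 5. Adjusted over the list alone these counts were 14 and 6, 6, 7 with 1 lower, and 6. These 4 lists passed camera with the preset correlation and not otherwise: adjusted p = 0.202 with an estimated correlation for activation, 0.0991 for the stress response, 0.31 for the naive and memory genes and 0.0844 for NF-kB targets. The NF-kB count was 0 without cssDNA 1, 1 without mock 1, mock 2 or cssDNA 3, 2 without cssDNA 2 and 3 without mock 3. The number of activation genes that rose was 4 without mock 1, mock 2, cssDNA 1 or cssDNA 2 and 5 without cssDNA 3. The naive and memory count was 3 without mock 1 or cssDNA 2.

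Interferon-stimulated genes did not rise as a list in cssDNA. Of 47 tested members 1 rose, TRIM22, and 3 fell, PARP9 (−0.40 ± 0.08, SE), DTX3L (−0.34 ± 0.07) and BST2 (−0.31 ± 0.08). The median log2 fold change was −0.14, and 2 rose and 6 fell adjusted over the list alone. ISG15 (−0.17 ± 0.13), MX1 (−0.03 ± 0.12), OAS1 (−0.55 ± 0.20), IFIT1 (−1.06 ± 0.54) and IFIH1 (0.07 ± 0.16) did not pass, nor did CGAS, the cytosolic DNA sensor (0.00 ± 0.07), TMEM173, the older symbol of its adaptor STING1 (−0.10 ± 0.08), CXCL10 (1.23 ± 0.54), CD69 (0.38 ± 0.16) or IFNG (0.32 ± 0.22). The list did not pass camera (adjusted p = 0.105, and 0.546 with an estimated correlation). The number that rose was 2 without mock 3. The number that fell was 1 without mock 1, mock 2 or cssDNA 2: DTX3L was not called without mock 1 (adjusted p = 0.0542), mock 2 (0.0766) or cssDNA 2 (0.0589). BST2 was not called without mock 1 (0.25), mock 2 (0.079), cssDNA 1 (0.0979), cssDNA 2 (0.0693) or cssDNA 3 (0.122). Conversely, CD69 was called without mock 3 (0.0386) and OAS1 without cssDNA 3 (0.0488), all in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 29 genes of cytosolic DNA sensing 4 fell and 0 rose (6 and 1 adjusted over the list alone). Those that fell were XRCC6, XRCC5, LRRFIP1 and PRKDC, the libraries of the groups overlapping for PRKDC, and not CGAS or TMEM173. The count was 0 without mock 1 or cssDNA 1, 1 without mock 2 or cssDNA 2 and 2 without cssDNA 3. Heat shock genes fell in 4 cases and rose in 1 of 18 (10 and 1 adjusted over the list alone), HSPD1 by −0.36 ± 0.04, adjusted p = 0.0739 with an estimated correlation. The higher heat shock count was 0 without mock 2 or cssDNA 1. The 13 mitochondrial mRNAs had a median of 0.72, with 2 called and 11 adjusted over the list alone, and adjusted p = 0.268 with an estimated correlation. All 13 were called without mock 3, and 0 without any other 1 of the 6 libraries. The 45 ribosomal protein genes had a median of 0.16, with 2 called, 8 adjusted over the list alone, and adjusted p = 0.381 with an estimated correlation. The count was 5 without mock 1, 1 without mock 3 or cssDNA 2 and 0 without mock 2 or cssDNA 1.

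In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 592 genes between cssDNA and mock, 238 higher and 354 lower, of which 32 changed at least 2-fold. Between the groups' libraries there was no overlap for 585 of the called genes, and for 23.3% of all tested genes, where chance gives 10%. Of the 28 lists tested, 14 passed camera and 6 held with an estimated correlation. The count fell to 300 without mock 1, 256 without mock 2, 347 without cssDNA 1 and 320 without cssDNA 2. Corrected for GC content and length there were 147 higher and 250 lower genes, against 256 and 380 from the same limma-trend test uncorrected. With the mitochondrial share as a covariate the count was 129, of which 114 were among the 592; all 592 genes kept their sign, the log2 fold changes had a median ratio of 0.906 to those without the covariate, and the standard errors a median ratio of 1.304.

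The comparison of dsDNA with mock asked what double-stranded DNA added to electroporation. Interferon-stimulated genes rose in a body. IFIT3, which codes for an antiviral protein (ENSG00000119917, GRCh38 chromosome 10, 89327894 to 89340971), went from 1.76 ± 0.450 CPM (SD, n = 3) in mock to 235 ± 37.3 in dsDNA, a log2 fold change of 7.04 ± 0.41 (SE). IFI44L (5.88 ± 0.49), IFIT1 (5.81 ± 0.54), IFIT2 (5.48 ± 0.25), RSAD2, which codes for the antiviral enzyme viperin (4.50 ± 0.20), DDX60 (3.78 ± 0.13), MX1 (2.86 ± 0.12), ISG15 (2.46 ± 0.13) and OAS1 (2.33 ± 0.20) rose too. Of the 47 tested members 43 rose and 0 fell, 44 adjusted over the list alone, with a median log2 fold change of 1.25. Adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 7.34e-15 for IFIT3, 1.06e-14 for MX1 and 1.16e-13 for ISG15. The list held in camera with a preset correlation (adjusted p = 3.32e-67) and with an estimated one (0.00127). The number of members called was 43 with any 1 of the 6 libraries left out.

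**Figure D1:**
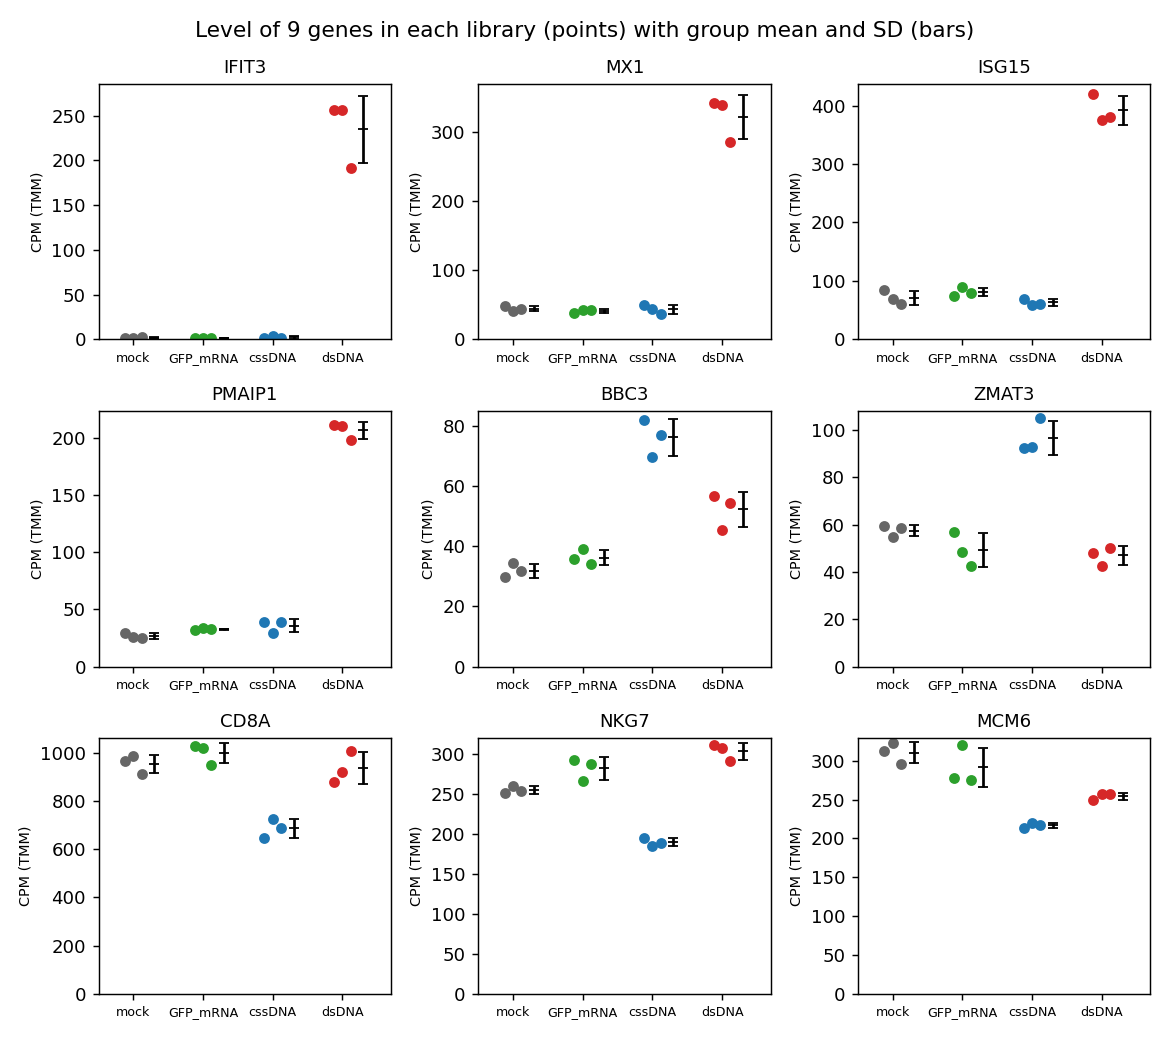
Level of 9 genes in CPM (scaled by TMM, axes from 0), with 1 point per library, 4 groups on the horizontal axis, and the group mean with its SD as a bar. IFIT3, MX1, ISG15 and PMAIP1 are highest in the 3 dsDNA libraries (IFIT3 mean 235 against 1.76 in mock), while BBC3 and ZMAT3 are highest, and CD8A, NKG7 and MCM6 lowest, in the cssDNA libraries.

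Most interferon genes had no counts. Of 21 genes for interferons of all types, 18 were at 0 counts in every library, IFNB1 among them; a count of 0 allows up to 3 counts per library, or 0.126 to 0.210 CPM, a floor that covers counting error only. IFNL1, coding for a type III interferon, had 22 counts in mock, 19 in GFP_mRNA, 0 in cssDNA and 16 in dsDNA over 3 libraries each, and IFNA21 had 0, 6, 2 and 0. IFNG, the interferon of activated T cells, was at 19.1 ± 1.66 CPM (SD, n = 3) in mock and 25.0 ± 3.15 in dsDNA, and the log2 fold change of 0.38 ± 0.22 (SE) did not pass (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.237).

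Some genes of RNA sensing rose in dsDNA. IFIH1, coding for the double-stranded RNA sensor MDA5, rose by 1.65 ± 0.16 (log2, SE, n = 3 per group), DDX58, the older symbol of RIGI, by 1.36 ± 0.15, DHX58 by 1.47 ± 0.16 and ZC3HAV1, an antiviral zinc finger protein, by 0.52 ± 0.05. Of 17 genes of RNA sensing 7 rose and 0 fell (8 and 1 adjusted over the list alone), but most others moved little: the median was 0.10, and adjusted p = 0.172 with an estimated correlation, against 0.00127 with the preset one. Of 29 genes of cytosolic DNA sensing 1 rose and 4 fell (4 and 8 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.269). CGAS had a log2 fold change of 0.29 ± 0.07 and did not pass edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.0793). PRKDC, a DNA-dependent kinase, fell by 0.59 on the log2 scale (SE 0.12). The number of DNA sensing genes that fell was 1 without mock 1, mock 2 or dsDNA 2 and 2 without dsDNA 1. The number that rose was 0 without mock 1, mock 2, mock 3 or dsDNA 3. Without dsDNA 3, 1 gene of RNA sensing fell.

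NF-kB targets and chemokines rose in dsDNA, as did some cytokines. Of 28 NF-kB targets 14 rose and 0 fell (16 adjusted over the list alone; median 0.56), such as TNFAIP3, a feedback inhibitor of NF-kB (1.33 ± 0.15, SE, n = 3 per group), NFKB2, a subunit of NF-kB itself (0.72 ± 0.07), and BIRC3, an inhibitor of apoptosis (1.03 ± 0.07). Of 12 chemokines 7 rose and 0 fell (8 adjusted over the list alone): CCL3 went from 6.30 ± 0.997 to 42.7 ± 6.41 CPM (SD), a log2 fold change of 2.76 ± 0.26, and CCL4 (1.60 ± 0.23), CCL5 (0.64 ± 0.07) and XCL1 (1.49 ± 0.32) rose. Of 13 T cell cytokines 6 rose and 1 fell (7 and 1 adjusted over the list alone), with IL13 at 2.11 ± 0.24, LIF at 1.22 ± 0.33, OSM at 0.55 ± 0.11 and TNF at 0.77 ± 0.20. The chemokine CXCL10 rose by 2.80 ± 0.54 with a mean of 2.93 CPM, at an adjusted p of 0.0352 (edgeR's quasi-likelihood test, Benjamini-Hochberg) that lay between 0.0525 and 0.139 with any 1 of the 6 libraries left out. NF-kB targets and chemokines held in camera with an estimated correlation (adjusted p = 0.00127 and 0.00683), and the cytokines did not (adjusted p = 0.129 with an estimated correlation). The chemokine count was 4 without mock 2, mock 3 or dsDNA 1. The number of cytokines that fell was 0 without mock 2, mock 3, dsDNA 2 or dsDNA 3.

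T cell activation genes rose in 15 of 32 cases and fell in 2 (20 and 4 adjusted over the list alone; median 0.44). CD38 (1.35 ± 0.11, SE, n = 3 per group), CD70 (1.27 ± 0.09), JUN (1.40 ± 0.19) and BATF (0.92 ± 0.12), a transcription factor of effector T cells, were among those that rose, and the list held with an estimated correlation (adjusted p = 0.0182). CD69, an early activation marker, rose by 0.53 ± 0.16 with an adjusted p of 0.0128 (edgeR's quasi-likelihood test, Benjamini-Hochberg), which was 0.0953 without mock 1, 0.0823 without dsDNA 1 and 0.0519 without dsDNA 2. LAG3 (1.36 ± 0.14) and ENTPD1 (0.80 ± 0.17), both of the checkpoint list, rose, while this list of 16 had 3 higher and 1 lower, likewise adjusted over the list alone, and adjusted p = 0.134 with an estimated correlation. Of 18 naive and memory genes 6 rose and 1 fell, likewise adjusted over the list alone, with CCR7 at 0.98 ± 0.06, CD27 at 0.71 ± 0.07 and TCF7 at 0.58 ± 0.07, and adjusted p = 0.334 with an estimated correlation. CD8A (−0.03 ± 0.06) and GZMB (0.17 ± 0.13) did not pass, though GZMB did without dsDNA 3 (adjusted p = 0.0303). The number of activation genes that fell was 1 without mock 1 or mock 2, and that of checkpoint genes that fell was 0 without mock 1, mock 2 or dsDNA 1. The 20 cytotoxic effectors went both ways, 4 higher and 2 lower (4 and 4 adjusted over the list alone), GZMA, coding for granzyme A, falling by 0.62 on the log2 scale (SE 0.13), and the list did not pass camera (adjusted p = 0.844). The count of higher effectors was 2 without mock 2, mock 3 or dsDNA 2, and that of lower ones 1 without mock 1, mock 2, dsDNA 2 or dsDNA 3.

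Among p53 targets, PMAIP1, which codes for the pro-apoptotic protein NOXA and is also induced by interferon signalling (ENSG00000141682, GRCh38 chromosome 18, 59899948 to 59904306), rose in dsDNA from 26.8 ± 2.48 to 206 ± 7.50 CPM (SD, n = 3; log2 fold change 2.94 ± 0.11, SE). BBC3 rose by 0.71 ± 0.10 and TRIM22 by 0.38 ± 0.03, and CDKN1A had 0.17 ± 0.12 and did not pass. Of the 33 members 5 rose and 0 fell (6 adjusted over the list alone; median 0.18), and the list held with an estimated correlation (adjusted p = 0.0107). Of 22 genes of apoptosis and pyroptosis 4 rose and 0 fell (5 and 2 adjusted over the list alone), BMF by 1.82 ± 0.20 and BCL2L11, coding for the pro-apoptotic protein BIM, by 0.89 ± 0.18, but the list did not pass camera (adjusted p = 0.0627). Cell cycle genes fell in 17 of 40 cases (25 adjusted over the list alone; median −0.25), MKI67 by 0.45 on the log2 scale (SE 0.08), and DNA repair genes in 6 of 33 (7 adjusted over the list alone; median −0.14). Both lists held with an estimated correlation (adjusted p = 0.00683 and 0.0284). The cell cycle count was 11 without mock 1 and 8 without mock 2, and the DNA repair count 1 without mock 2 and 2 without dsDNA 1 or dsDNA 3.

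Some stress and antigen presentation genes moved as well. PPP1R15A (0.97 ± 0.10, SE, n = 3 per group), WARS, a tRNA synthetase that interferon also induces (0.75 ± 0.07), DDIT3 (1.23 ± 0.18) and ATF3 (0.89 ± 0.15) rose among 6 of 26 genes of the integrated stress response (8 higher and 1 lower adjusted over the list alone), adjusted p = 0.172 with an estimated correlation. Of 20 genes of antigen presentation 8 rose (9 adjusted over the list alone), B2M, the light chain of HLA class I, by 0.41 ± 0.04 and HLA-F by 0.71 ± 0.10, adjusted p = 0.0617 with an estimated correlation. Of 18 heat shock genes 5 fell (5 lower and 1 higher adjusted over the list alone), HSPH1 by −0.36 ± 0.02, adjusted p = 0.0617 with an estimated correlation, and the count was 3 without mock 2. Among the genes that fell were B3GAT1, coding for the enzyme that makes the CD57 epitope (−3.17 ± 0.30, with 0.529 CPM in dsDNA), FGL2 (−2.01 ± 0.25) and TNFRSF10D, a decoy receptor for TRAIL (−1.73 ± 0.53). The 45 ribosomal protein genes had a median of 0.13 with 3 higher and 5 lower (17 and 6 adjusted over the list alone), adjusted p = 0.785 with an estimated correlation. The higher count was 12 without mock 1, 0 without mock 2 and 1 without mock 3, dsDNA 1 or dsDNA 3. The lower count was 3 without mock 1 and 2 without mock 2 or dsDNA 2.

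In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1133 genes between dsDNA and mock, 579 higher and 554 lower, of which 180 changed at least 2-fold. The libraries of the groups did not overlap for 1118 of them, and for 24.4% of all tested genes, where chance gives 10%. Of 28 lists 15 passed camera and 7 held with an estimated correlation. The count was 652 without mock 2. Correcting the values for GC content and transcript length, added after the data were seen, gave 582 higher and 245 lower genes, against 574 and 573 from the same limma-trend test without the correction.

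**Figure D2:**
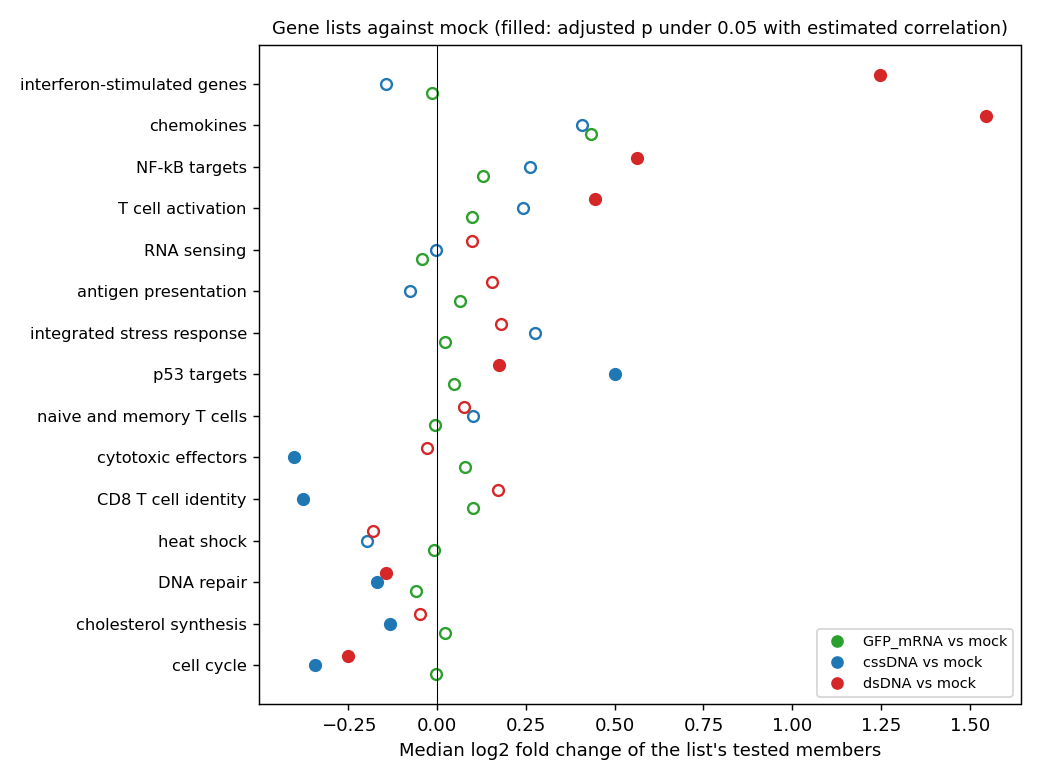
Median log2 fold change against mock (horizontal axis) of the tested members of 15 gene lists (vertical axis) for GFP_mRNA, cssDNA and dsDNA, each group of 3 libraries against 3. Filled points are lists that passed camera with an estimated correlation: interferon-stimulated genes reach 1.25 in dsDNA, p53 targets 0.50 in cssDNA, and cell cycle genes −0.34 in cssDNA and −0.25 in dsDNA.

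A direct test of dsDNA against cssDNA asked in which genes the DNA forms differed. Interferon-stimulated genes were higher in dsDNA in 43 of 47 cases and lower in 1 (likewise adjusted over the list alone; median 1.31), IFIT1 by 6.87 ± 0.54 (log2, SE, n = 3 per group), MX1 by 2.89 ± 0.12 and ISG15 by 2.63 ± 0.13. PLCG2, a signalling phospholipase, was at 110 ± 2.48 CPM (SD) in dsDNA and 9.22 ± 2.12 in cssDNA, a difference of 3.58 ± 0.28. Of 28 NF-kB targets 9 were higher (14 adjusted over the list alone), LTA by 0.98 ± 0.14, of 12 chemokines 3 (5 adjusted over the list alone), CCL3 by 1.80 ± 0.26, and of 20 genes of antigen presentation 12 (14 adjusted over the list alone), TAP1, a peptide transporter, by 0.62 ± 0.06. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 1.27e-14 for MX1 and 2.11e-11 for PLCG2. These 4 lists held with an estimated correlation (adjusted p = 0.00108, 0.00398, 0.0122 and 0.0207). The lower interferon count was 0 without cssDNA 2, cssDNA 3, dsDNA 1 or dsDNA 3. The NF-kB count lay between 6 and 8 and that of antigen presentation between 8 and 12 with any 1 library left out.

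Targets of p53 were lower in dsDNA than in cssDNA in 16 of 33 cases and higher in 2 (22 and 2 adjusted over the list alone; median −0.39). ZMAT3 differed by −1.04 ± 0.11 (log2, SE, n = 3 per group), SESN1, a stress-induced sestrin, by −0.86 ± 0.08 and DDB2, a sensor of ultraviolet damage, by −0.46 ± 0.07, whereas PMAIP1 was higher by 2.53 ± 0.11. The list held with an estimated correlation (adjusted p = 0.00108). The lower count was 10 without cssDNA 1, cssDNA 2 or cssDNA 3 and 9 without dsDNA 1 or dsDNA 3. The higher count was 1 without cssDNA 2, cssDNA 3, dsDNA 1 or dsDNA 2. The CD8 and cytotoxic genes were higher in dsDNA: CD8A by 0.45 ± 0.06, CD8B by 0.62 ± 0.10, NKG7 by 0.68 ± 0.04, CTSW by 0.80 ± 0.06 and PRF1 by 0.43 ± 0.05, with 5 of 11 CD8 identity genes higher, likewise adjusted over the list alone (adjusted p = 0.0122 with an estimated correlation), and 7 of 20 cytotoxic effectors (8 higher and 1 lower adjusted over the list alone; adjusted p = 0.0617 with an estimated correlation). CD4 differed by −0.53 ± 0.09 and CCR4, a homing receptor found on CD4 T cells, by −0.40 ± 0.06, while the CD4 identity list had 2 higher and 2 lower of 11, likewise adjusted over the list alone, and did not pass (adjusted p = 0.479). The higher CD4 count was 1 without cssDNA 2, cssDNA 3 or dsDNA 2. LAG3 was higher by 1.61 ± 0.14 and ENTPD1 by 1.02 ± 0.17, with 4 of 16 checkpoint receptors higher (5 adjusted over the list alone; adjusted p = 0.0578 with an estimated correlation).

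In all, 867 genes differed between dsDNA and cssDNA in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 521 higher and 346 lower in dsDNA, of which 154 changed at least 2-fold. The libraries did not overlap for 854 of them, and for 22.2% of all tested genes, where chance gives 10%. Of 28 lists 18 passed camera and 6 held with an estimated correlation. The count was 532 without cssDNA 2, and 421 with the mitochondrial share as a covariate. Corrected for GC content and length there were 722 higher and 234 lower genes, against 561 and 390 from the same limma-trend test uncorrected.

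Against mock, 234 genes were called in the same direction in cssDNA and dsDNA, 108 higher and 126 lower, and 12 in opposite directions. Among the shared genes were BBC3 (1.26 in cssDNA and 0.71 in dsDNA), JUN (1.35 and 1.40), FOS (1.72 and 1.66), FOSB (1.46 and 1.32), BMF (1.20 and 1.82), PPP1R15A (0.87 and 0.97), ATF3 (0.95 and 0.89), CCR7 (0.53 and 0.98) and FGFBP2 (0.88 and 0.73). Independent lists of these sizes would share 8.71 higher and 12.4 lower genes. In 40 simulations all groups were drawn from 1 mean and both DNA groups were set against 1 simulated mock. The number shared there was at most 3, with a mean of 0.400. With no change drawn in, few calls are made by construction, so this number does not measure what shared mock libraries add to the 234. The log2 fold changes of all tested genes had a correlation across genes, which are not independent replicates, of 0.258, against a simulated mean of 0.275 and maximum of 0.307, and the same sign in 63.4% of genes against 62.5% simulated. Their covariance was 0.121 against 0.0910 simulated, a difference of 0.0301. The 3 mock libraries cannot be parted into 2 sets of 2, and the overlap was not counted with GFP_mRNA as the control of 1 DNA group. The share of the shared calls that comes from the shared controls was thus not measured. The number shared was 130 without mock 1, 103 without mock 2, 146 without cssDNA 1 and 151 without cssDNA 2.

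**Figure D3:**
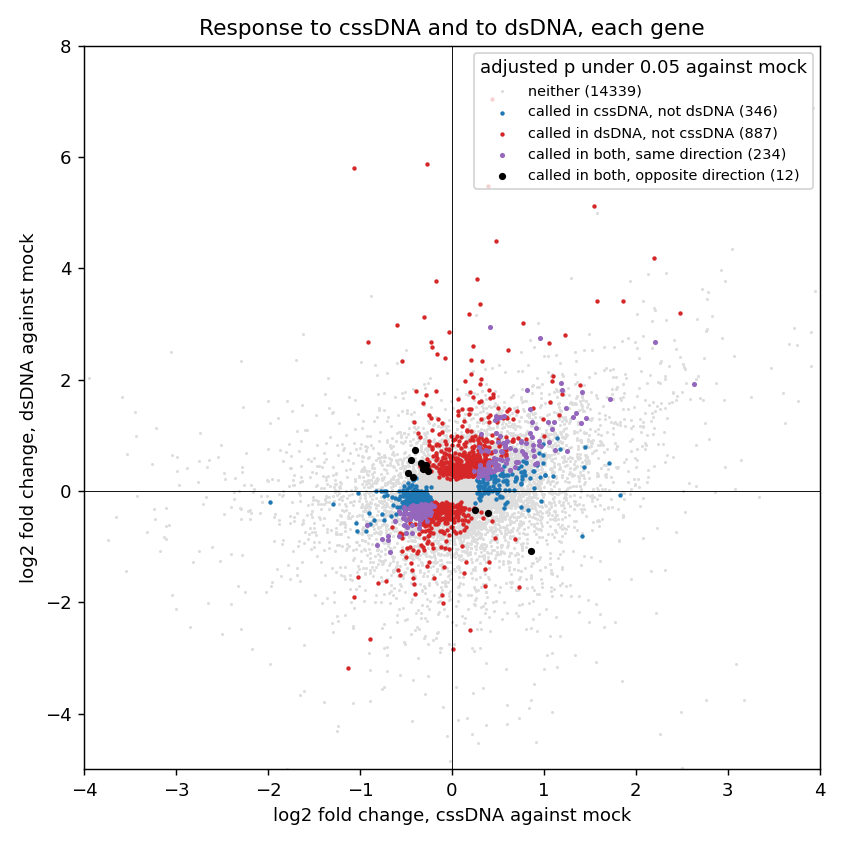
Log2 fold change of each tested gene in cssDNA against mock (horizontal axis) and in dsDNA against mock (vertical axis), from 3 libraries per group; 100 genes lie outside the axes. The 887 genes called in dsDNA and not in cssDNA spread along the vertical axis, the 346 called in cssDNA and not in dsDNA along the horizontal one, 234 were called in both in the same direction and 12 in opposite directions.

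The DNA groups were also set against GFP_mRNA in place of mock. In dsDNA, 43 of 47 interferon-stimulated genes were higher (44 adjusted over the list alone), IFIT3 by 6.97 ± 0.41 (log2, SE, n = 3 per group) and MX1 by 2.96 ± 0.12, as were 11 of 28 NF-kB targets (16 adjusted over the list alone) and 6 of 12 chemokines (6 adjusted over the list alone), CCL3 by 2.33 ± 0.26. PMAIP1 was higher by 2.66 ± 0.11, CD38 by 1.35 ± 0.11, LAG3 by 1.21 ± 0.14 and CCR7 by 0.91 ± 0.06, while 15 of 40 cell cycle genes were lower (23 lower and 1 higher adjusted over the list alone), MKI67 by −0.36 ± 0.08. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 7.65e-15 for IFIT3 and MX1 and 5.04e-14 for PMAIP1. The number of genes called was 1000, with 501 higher, 499 lower and 175 changed at least 2-fold. In all, 15 lists passed camera and 7 held with an estimated correlation, namely interferon-stimulated genes, NF-kB targets, chemokines, p53 targets, T cell activation, cell cycle and heat shock. The count of genes was 665 without GFP_mRNA 1 and 647 without GFP_mRNA 3. The cell cycle count was 8 without GFP_mRNA 2 or dsDNA 1 and 9 without GFP_mRNA 3, the NF-kB count 7 without GFP_mRNA 2, and the chemokine count 3 without dsDNA 2.

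In cssDNA against GFP_mRNA, 20 of 33 p53 targets were higher and 0 lower (24 adjusted over the list alone), BBC3 by 1.07 ± 0.10 (log2, SE, n = 3 per group), ZMAT3 by 0.97 ± 0.11 and XPC, a DNA damage recognition gene, by 0.58 ± 0.06. Cell cycle genes were lower in 27 of 40 cases (33 adjusted over the list alone), CD8 identity genes in 5 of 11 (7 adjusted over the list alone), CD8A by −0.54 ± 0.06, and cytotoxic effectors in 8 of 20 with 1 higher (9 and 1 adjusted over the list alone), PRF1 by −0.58 ± 0.05. FOS (1.74 ± 0.31), JUN (1.19 ± 0.19) and PPP1R15A (0.89 ± 0.10) were higher, and of 47 interferon-stimulated genes 1 was higher and 5 lower (2 and 12 adjusted over the list alone; camera adjusted p = 0.156). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 8.78e-06 for BBC3 and 5.94e-05 for CD8A. The number of genes called was 712, with 251 higher, 461 lower and 30 changed at least 2-fold. In all, 11 lists passed camera and 7 held with an estimated correlation, namely p53 targets, cell cycle, CD8 identity, cytotoxic effectors, DNA repair, heat shock and cholesterol synthesis. The CD8 identity and cytotoxic effector lists share members, so these 7 are not independent. The count of genes was 448 without GFP_mRNA 1, 351 without GFP_mRNA 2, 315 without cssDNA 2 and 417 without cssDNA 3, and 471 with the mitochondrial share as a covariate. Without cssDNA 2 the p53 count was 13 and the cell cycle count 15, without GFP_mRNA 1 the CD8 count was 3, and the number of lower interferon-stimulated genes was 2 without GFP_mRNA 2, cssDNA 2 or cssDNA 3. The number of higher ones was 2 without cssDNA 1.

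Tested over all 4 groups at once, 1670 genes differed between at least 1 pair of groups (edgeR's quasi-likelihood test of 3 coefficients, Benjamini-Hochberg). The count was 537 with the libraries of replicate number 1 left out of every group, 509 without number 2 and 1142 without number 3.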

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

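The tests of other blood cells, of a lower share of CD8 T cells and of the mitochondrial share for the p53 targets were chosen after the result was seen. The 12 genes below were picked because they were called against mock in cssDNA and in dsDNA with opposite signs. That choice nearly fixes the outcome of a direct test between the DNA groups, so such a test would add no support.

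Of these genes 9 were higher in dsDNA than in cssDNA. The difference of the log2 fold changes was 1.14 for PARP9 (−0.40 in cssDNA and 0.74 in dsDNA against mock), 0.99 for OSM (−0.44 and 0.55), 0.84 for DTX3L (−0.34 and 0.50), 0.80 for CTSW (−0.48 and 0.32), 0.78 for BST2 (−0.31 and 0.46), 0.75 for ABI3 (−0.28 and 0.47), 0.70 for CCDC85B (−0.32 and 0.39), 0.68 for NKG7 (−0.43 and 0.25) and 0.62 for TAP1 (−0.26 and 0.36). The other 3 were lower in dsDNA: CACNA1I by −1.94 (0.86 and −1.08), SORL1 by −0.78 (0.39 and −0.39) and LMNA by −0.60 (0.25 and −0.35). PARP9, DTX3L, BST2 and TAP1 respond to interferon, and CTSW and NKG7 belong to cytotoxic cells.

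The rise of interferon-stimulated genes in dsDNA was weighed against technical explanations. With every library thinned to the smallest total, 43 members were called higher, and the fewest called with any 1 library left out were 43, which argues against depth or a single library. Monocytes would bring LYZ, S100A8, S100A9, CD14, FCN1 and CST3, whose summed level was 1.18 ± 0.596 CPM (SD, n = 3) in dsDNA and 2.00 ± 0.222 in mock. Dendritic cells need not express all of these genes, so the sum does not test for them. A response of the T cells to double-stranded DNA may explain the rise, as a hypothesis found on these data and not tested. Which sensor would start it was not tested either. Whether the form of the DNA or another property of what was delivered caused the rise stays open, since no group received other double-stranded DNA.

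The fall of CD8 and cytotoxic genes in cssDNA may reflect the share of CD8 T cells, the RNA quality or a bias of sequence content. A lower share with no other change would raise genes expressed in CD4 T cells alone by 1 factor. Of the 36 pairs of CD4 identity genes, 16 moved apart by more than their spread, with log2 fold changes from −0.16 to 0.72. Listed genes that CD8 T cells also express would move by another factor, so these pairs cannot decide the question. CD8A minus CD8B was −0.06 ± 0.06 (SE). With the mitochondrial share as a covariate CD8A changed by −0.42 ± 0.08 (adjusted p = 0.00862, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), against −0.48 ± 0.07 without it (SE here from the F statistic), and after correction for GC content and length by −0.54 ± 0.10, so that neither explains it alone. A lower share of CD8 T cells, alone or together with a change within CD4 T cells, stays open.

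The rise of p53 targets and the fall of cell cycle genes in cssDNA was weighed against the same trends. With the mitochondrial share as a covariate the median of the p53 targets was 0.50, as without it, though 10 in place of 21 members were called, and after correction for GC content and length the cell cycle median was −0.37, against −0.35 before. With the covariate the cell cycle median was −0.31 and 4 in place of 22 members were called. Over the 592 called genes, the log2 fold changes shrank to a median ratio of 0.906 and the standard errors grew by a median ratio of 1.304, so calls ended mainly because the errors grew. A p53 response to cssDNA may be a biological explanation. Electroporation was common to mock and cssDNA, so it does not by itself explain a difference between them. Whether the form of the DNA or another property of what was delivered caused the response stays open, since no group received other DNA of that form.

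Other splits of the same libraries were tested for the number of genes called in each comparison and over the 4 groups. The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05: 1 split, the real one, gave as many genes in cssDNA against mock (592, highest other 0), dsDNA against mock (1133, highest other 0), dsDNA against cssDNA (867, highest other 0), dsDNA against GFP_mRNA (1000, highest other 0) and cssDNA against GFP_mRNA (712, highest other 0). In GFP_mRNA against mock 2 splits gave as many as the real 1, and the highest other gave 40. That split parts mock 1, mock 2 and GFP_mRNA 2 from the rest, the libraries with the 3 lowest mitochondrial shares of the 6, and points to a structure of the samples. Over the 4 groups 1 of 100 splits gave as many genes, the real one with 1670 against 67 in the highest other. The share of 0.01 is the smallest that 100 splits can give. For that count it argues against a chance arrangement of these libraries, but not against a culture or handling common to a group's libraries.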

How the results depend on the processing

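Quality weights, the mitochondrial covariate and the GC and length correction were chosen after the data were seen. Where a named gene was called in the main fit or under an alternative, it kept its direction between them (0 reversed). The direction of genes called in neither was not counted. A fold of at least 2 was left out of these counts, as was any alternative in which a gene was not tested. Under all the others, 27 of 86 genes called in cssDNA against mock stayed called. So did 69 of 107 in dsDNA against mock, 63 of 98 in dsDNA against cssDNA, 65 of 104 in dsDNA against GFP_mRNA and 48 of 82 in cssDNA against GFP_mRNA. Counts of called genes moved by over 1.5 times as follows; the cause was not tested, except that a fold minimum lowers a count by construction. In GFP_mRNA against mock (1) there were 30 with no expression filter, 2 with DESeq2, 20 with quality weights and 1 to 18 with 1 library left out. In cssDNA against mock (592) there were 32 at a fold of at least 2, 955 with no filter, 1055 with DESeq2, 1287 with quality weights, 129 with the covariate and 256 to 645 with 1 library left out. In dsDNA against mock (1133) there were 180 at a fold of at least 2 and 652 to 1002 with 1 library left out. In dsDNA against cssDNA (867) there were 154 at a fold of at least 2, 421 with the covariate and 532 to 755 with 1 library left out. In dsDNA against GFP_mRNA (1000) there were 175 at a fold of at least 2 and 647 to 912 with 1 library left out. In cssDNA against GFP_mRNA (712) there were 30 at a fold of at least 2, 1090 with no filter, 1168 with DESeq2, 1104 with quality weights, 471 with the covariate and 315 to 567 with 1 library left out. Over the 4 groups (1670) there were 2681 with quality weights, 197 at a fold of at least 2 and 509 to 1142 with 1 replicate number left out, and the overlap (234) was 14 at a fold of at least 2, 443 with DESeq2 and 103 to 244 with 1 library left out. Lists called fell with an estimated correlation from 5 to 0 in GFP_mRNA against mock, 14 to 6 in cssDNA against mock, 15 to 7 in dsDNA against mock, 18 to 6 in dsDNA against cssDNA, 15 to 7 in dsDNA against GFP_mRNA and 11 to 7 in cssDNA against GFP_mRNA; in GFP_mRNA against mock there were 2 with the covariate and 2 to 6 with 1 library left out. The GC and length correction gave 454 higher and 248 lower genes in dsDNA against GFP_mRNA (504 and 522 without it) and 125 and 373 in cssDNA against GFP_mRNA (279 and 505). A block on the replicate number gave 1, 610, 1092, 839, 943 and 706 calls in the comparisons, in the order of the lists above. It gave 1652 over the 4 groups and an overlap of 239. The 18 pairs of libraries with 1 number had correlations of −0.0742 to 0.102, and 4 of 12 libraries correlated best with their own number. These values show no pairing by number, but with 3 libraries per group they cannot exclude one. Thinned to 14284832 counts per library, the comparisons gave 1, 587, 1137, 882, 988 and 704 calls in that order, and depth limits what can be said of genes near 0.126 to 0.210 CPM, such as the interferon genes.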

Other observations

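Of 30 genes of glycolysis and hypoxia 1 rose and 4 fell in cssDNA against mock (3 and 8 adjusted over the list alone; camera adjusted p = 0.2), LDHA, which makes lactate, by −0.31 ± 0.07 (log2, SE, n = 3 per group), a call lost without mock 2 or cssDNA 2 (adjusted p = 0.0902 and 0.0557 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The higher count was 0 with any 1 of the 6 libraries left out, and the lower count was 0 without mock 2, 1 without mock 1, cssDNA 2 or cssDNA 3 and 2 without cssDNA 1. In dsDNA against mock 2 rose and 1 fell (4 and 6 adjusted over the list alone; adjusted p = 0.786), BHLHE40, a transcription factor induced by hypoxia and by activation, by 0.77 ± 0.03, and LDHA changed by −0.36 ± 0.07; the higher count was 1 without mock 3 or dsDNA 2, and the lower 2 without mock 3 or dsDNA 3. Genes of cholesterol synthesis fell in 4 of 27 cases in dsDNA against mock (7 adjusted over the list alone; adjusted p = 0.0913), FASN, fatty acid synthase, by −0.34 ± 0.08. Of 20 genes of the unfolded protein response none was called in edgeR against mock in cssDNA, 3 of them being lower adjusted over the list alone, and the list was lower in camera, adjusted p = 0.19 with an estimated correlation. In dsDNA against cssDNA 3 of them were higher (5 and 1 lower adjusted over the list alone; adjusted p = 0.211 with an estimated correlation), HSPA5, the chaperone BiP, by 0.24 ± 0.03; the count was 1 without cssDNA 1.

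Of 20 genes of antigen presentation 3 fell in cssDNA against mock (5 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.112), PSMB8, a subunit of the immunoproteasome, by −0.39 ± 0.09 (log2, SE, n = 3 per group), and the count was 1 without mock 1, mock 2, cssDNA 1, cssDNA 2 or cssDNA 3. In cssDNA against mock 1 of 12 chemokines rose (camera adjusted p = 0.162), 1 of 13 cytokines fell (0.295), 2 of 22 apoptosis genes rose and 2 fell (0.847; their median was −0.03), and 1 of 16 checkpoint receptors fell (0.162), namely CD244 by −0.71 ± 0.06. Without mock 2 or cssDNA 1 the chemokine and cytokine counts were 0, without mock 1 or cssDNA 2 the higher apoptosis count was 1, and the lower was 0 without mock 1, mock 2, cssDNA 1 or cssDNA 2 and 1 without cssDNA 3. Of 24 histone genes 1 rose in cssDNA (0.162) and 1 in dsDNA (0.321), counts that were 0 without any library but cssDNA 3 and dsDNA 2. Of 11 CD4 identity genes 2 rose and 1 fell in dsDNA against mock (adjusted p = 0.595), and of 11 CD8 identity genes likewise 2 and 1 (0.311). Without single libraries the higher counts of these lists were 0 to 1 for CD4, being 0 without mock 2, and 1 for CD8 without any but dsDNA 3; the lower CD4 count was 0 without any but dsDNA 3, where it was 2, and the lower CD8 count 0 without mock 1, mock 2, dsDNA 2 or dsDNA 3. Of 7 tested B cell markers, 2 were higher in dsDNA than in GFP_mRNA (adjusted p = 0.0929 with an estimated correlation), CD79A by 2.02 ± 0.44 and MS4A1 by 3.01 ± 0.55, and 1 in cssDNA than in GFP_mRNA (adjusted p = 0.13 with an estimated correlation), MS4A1 by 3.72 ± 0.55 at 3.26 CPM against 0.247, and in dsDNA against mock 1 rose (0.0913), a count that was 0 without any library but dsDNA 2; without GFP_mRNA 1 the count in dsDNA against GFP_mRNA was 1, MS4A1 having an adjusted p of 0.0519 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 13 markers of natural killer cells 1 rose in dsDNA against mock (0.349). Of 22 markers of monocytes and dendritic cells 5 had enough counts to be tested, and none was called in edgeR's quasi-likelihood test. Of 14 platelet and erythroid markers 1 had enough counts to be tested and was not called.

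Of the 13 mitochondrial mRNAs, 3 were lower in dsDNA than in cssDNA (9 adjusted over the list alone; median −0.72), and adjusted p = 0.496 with an estimated correlation. They were MT-ND6 (−1.09 ± 0.41, log2, SE, n = 3 per group), MT-CO1 (−0.95 ± 0.38) and MT-ND5 (−1.03 ± 0.44). The count was 0 without cssDNA 3 or dsDNA 1 and 1 without dsDNA 2. In dsDNA against mock 0 of them were called in edgeR, and 11 were higher without mock 3.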
